A study of Rattus norvegicus with 4 samples.

How the data were processed

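The measurement was RNA from rat aortic smooth muscle cells, per the labels plated at 10000 cells per cm2 in 10% fetal bovine serum for 24 h and kept for 72 h in medium without serum and insulin. Per the labels, 2 samples then received PDGF-BB at 30 ng/mL and 2 the vehicle, 0.2% bovine serum albumin in 10 mM acetic acid, for 3 h. Total RNA was extracted on spin columns and labelled with biotin as cRNA for Affymetrix arrays, per the labels' protocols. Groups and replicate numbers came from the sample titles and source names.

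The deposited values are probe set intensities on a linear scale, 1 table of 4 columns, as the values themselves show: they are above 0 with decimals, and the highest on each array was 16721 to 17218. The software, the background correction and the scaling between arrays that the authors used are not given in the sources used here. The direction of the contrast is set by the groups. The table gives no detection calls. As a yardstick of background, the highest intensity among 27 Bacillus control probe sets was taken, 80.3. The labels do not say whether these transcripts were spiked in, so this is a rough guide. Between 41.0% and 41.8% of probe sets per array were at or below it, and 9128 probe sets had means at or below it in both groups.

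Of 23764 probe sets, 57 Affymetrix control probe sets were left out and 23707 tested. A platform annotation dated 2016 gave 1 gene symbol for 17279 probe sets, several for 373 and none for 6055, which are unnamed here. Through a table of reference genes, 17223 of the 17279 probe sets matched a current gene identifier, and 0 symbols changed. A gene was represented by the probe set with the highest mean over all 4 arrays, giving 12922 genes, 3256 of them with several probe sets. Among these, 596 genes had at least 2 probe sets called, and in 10 of these the calls went in both directions. Suffixes s and x in a probe set name mark probes that can match transcripts of more than 1 gene. Of the named genes, Smtnl2, Plaur and Pdgfrb rest on a probe set of the s type.

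Values were tested as log2(intensity + 16) without further scaling. The offset of 16 damps noise near background and understates the change of dim genes. The design was written for values on a log2 scale, with this transformation planned for linear values, which the table proved to hold. Fits used lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 23707 probe sets and a threshold of 0.05. With 2 residual degrees of freedom, the variance prior had 2.40 degrees of freedom and an SD of 0.114. Fold changes are PDGF-BB minus vehicle on the log2 scale.

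There were 21 gene lists of 528 symbols, of which 470 distinct genes were measured; symbols without a probe set of a single symbol were not analysed here. Lists were tested with camera of limma with a preset correlation of 0.01 between genes, adjusted over the 21 lists, and again with the correlation estimated per list. With the estimated correlation no list passed the threshold. The lowest adjusted p was 0.232, and 2 lists had an unadjusted p under 0.05. This form of camera rests on the 2 residual degrees of freedom, so it has little power here. Immediate early factors and inflammatory genes had estimated correlations of 0.0010 and 0.0040, below the preset 0.01. Their camera p still rose from 6.81e-17 to 0.0115 and from 7.70e-10 to 0.0221. For these 2 lists the lost call therefore does not by itself point to correlation between genes. Other lists had estimates far above the preset: 0.68 for ribosome biogenesis, 0.41 for replication and mitosis and 0.34 for phenotype regulators. There the preset may understate the p-value, and correlation and low power cannot be told apart as reasons for a lost call. The rule for named genes took the 12 largest called increases and the 12 largest called decreases with both PDGF-BB arrays beyond both vehicle arrays, up to 4 members of each list with the smallest p, and 13 genes fixed by name, which made 112 genes. The samples, designs, lists, this rule and the alternatives were chosen before the data were examined, except cyclic loess normalization, which was added after an offset between the arrays that varied with intensity had been seen.

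The procedure was tested on simulated data with the real means and spreads for PDGF-BB against vehicle with 2 arrays each, over 23707 probe sets, 200 of them changed. It recovered 3 of 68 probe sets changed by 0.5 on the log2 scale, 58 of 66 changed by 1 and 66 of 66 changed by 2, and called 10 of 23507 unchanged ones. A simulated raised list was called and 0 of 20 unchanged lists were. The simulated noise was independent between probe sets, while the estimated correlation in the data reached 0.68, for ribosome biogenesis. The simulation therefore does not test the list calls under correlation between genes. Far fewer probe sets were changed there than the 5779 called in the data, which makes the adjusted threshold stricter, so the recovery of small changes does not carry over.

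No pair of arrays was a duplicate: at most 0.831% of values were identical, and the median absolute log2 difference was 0.101 within the vehicle pair, 0.167 within the PDGF-BB pair and 0.263 to 0.302 between groups. The 18 hybridization control probe sets had log2 fold changes between -0.06 and 0.09, and 0 of them were called by limma. Those of the 27 Bacillus controls lay between -0.43 and 0.36, and limma called 1, a lys probe set at -0.43 (adjusted p 0.0308). Alternatives were quantile, median and cyclic loess scaling, filters on dim probe sets, an intensity trend or robust variance prior, the replicate number as a block, leaving out each array, pseudocounts of 1 and 64, the mean of all probe sets of a gene, a 2-fold minimum and an adjusted p of 0.10.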

Results

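RNA was measured in rat aortic smooth muscle cells, the contractile cells of the arterial wall, which leave growth arrest and lose contractile gene expression in the process called phenotypic modulation. The cells were grown in 10% serum for 24 h and starved of serum for 72 h. They then received platelet-derived growth factor BB (PDGF-BB), a mitogen for these cells, at 30 ng/mL, or its vehicle, for 3 h. Each group had 2 Affymetrix arrays, and the study set out to find early genes of phenotypic modulation. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays only, which may be technical. The median probe set intensity was 145 and 148 on the vehicle arrays and 144 and 132 on the PDGF-BB arrays. Across probe sets, the log2 values of the vehicle pair had a Pearson correlation of 0.995 and those of the PDGF-BB pair 0.993, against 0.959 to 0.963 between groups. Probe sets are not independent replicates. The number of arrays limits the precision of all values.

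The comparison asked which genes differed after 3 h of PDGF-BB. Of 12922 genes, 1601 were higher and 1969 lower with PDGF-BB at an adjusted p under 0.05 by limma, 27.6% of the genes measured. At least 2-fold changes were seen in 590 higher and 484 lower genes, and at least 16-fold changes in 25 higher and 2 lower genes. At the level of probe sets, 2712 of 23707 were higher and 3067 lower. In 67.5% of all genes, both PDGF-BB arrays lay on the same side of both vehicle arrays, a separation that chance gives for 33.3% of genes. The counts depended on which array was left out. Without vehicle replicate 1 the fit called 786 genes, without vehicle replicate 2 841, without PDGF-BB replicate 1 2683 and without PDGF-BB replicate 2 1889. All 4 of these fits have a single array in 1 group. The balance of the directions turned as well: 44.8% of the genes called with all arrays were higher, against 62.1% and 62.0% without vehicle replicate 1 or 2, 39.4% without PDGF-BB replicate 1, 54.6% without PDGF-BB replicate 2 and 52.6% with array medians subtracted. Of the genes named below and called, 32 have several probe sets, and in 13 of them limma called some but not all, 0 in the opposite direction: 1 of 2 for Nr4a3, Pik3ip1, Plaur, Myh11, Fos and Pdgfrb, 2 of 3 for Egfr and Flt1, 2 of 4 for Synpo2, 3 of 4 for Ldb3 and Nolc1, 2 of 5 for Klf2 and 3 of 5 for Cdc20.

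The largest increase among the named genes was that of Phlda1, a gene induced by growth factor signalling. Its intensity rose from 18.9 ± 1.58 with vehicle to 2994 ± 27.5 with PDGF-BB (SD, n = 2), a log2 fold change of 6.43 (SE 0.09). Dusp5 and Dusp6, phosphatases that inactivate ERK, rose by 5.46 (SE 0.09) and 5.41 (SE 0.10) on the log2 scale. Serpinb2, an inhibitor of plasminogen activators, rose by 5.42 (SE 0.13), Fosl1, an AP-1 subunit, by 5.33 (SE 0.11) and the orphan nuclear receptor Nr4a3 by 5.26 (SE 0.11). Tcim (5.33), the retinol dehydrogenase Dhrs9 (5.23), Palldl1 (5.22), the chromatin protein Hmga1 (5.17), the zinc-finger factor Egr2 (5.15) and the protease inhibitor Serpinb1a (5.03) completed the 12 largest increases. These 12 genes rose 32.8- to 86.3-fold on the log2(intensity + 16) scale, with limma adjusted p-values of at most 0.000710. In 11 of the 12 the vehicle mean was at or below 80.3, the highest intensity of a Bacillus control probe set, so the size of the increase depends on values near background.

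The largest decrease was that of Rnf122, a RING-finger ubiquitin ligase, from 1109 ± 7.04 (SD, n = 2) to 28.8, the mean of 19.6 and 38.0 on the 2 PDGF-BB arrays, a log2 fold change of -4.68 (SE 0.22). Pik3ip1, an inhibitor of phosphoinositide 3-kinase, fell by 4.03 (SE 0.12), and the Notch ligand Jag1 fell by 3.66 (SE 0.12), from 4177 ± 331 to 316 ± 27.8. Cavin2, a component of caveolae, and the cytokine Il15 each fell by 3.39 (SE 0.12 and 0.10). Otub2 (-3.32), Lurap1l (-3.19), Ccno (-3.18), Palmd (-3.14), Pou3f3 (-3.12), Smtnl2 (-3.12) and Arhgef28 (-2.90) followed. The 12 genes were 7.47- to 25.7-fold lower, with limma adjusted p-values of at most 0.00199. In 9 of the 12 the PDGF-BB mean was at or below 80.3, so the size and order of these decreases depend on values near background. All 24 of these genes stayed called in each of the 4 fits that left out 1 array.

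**Figure D1:**
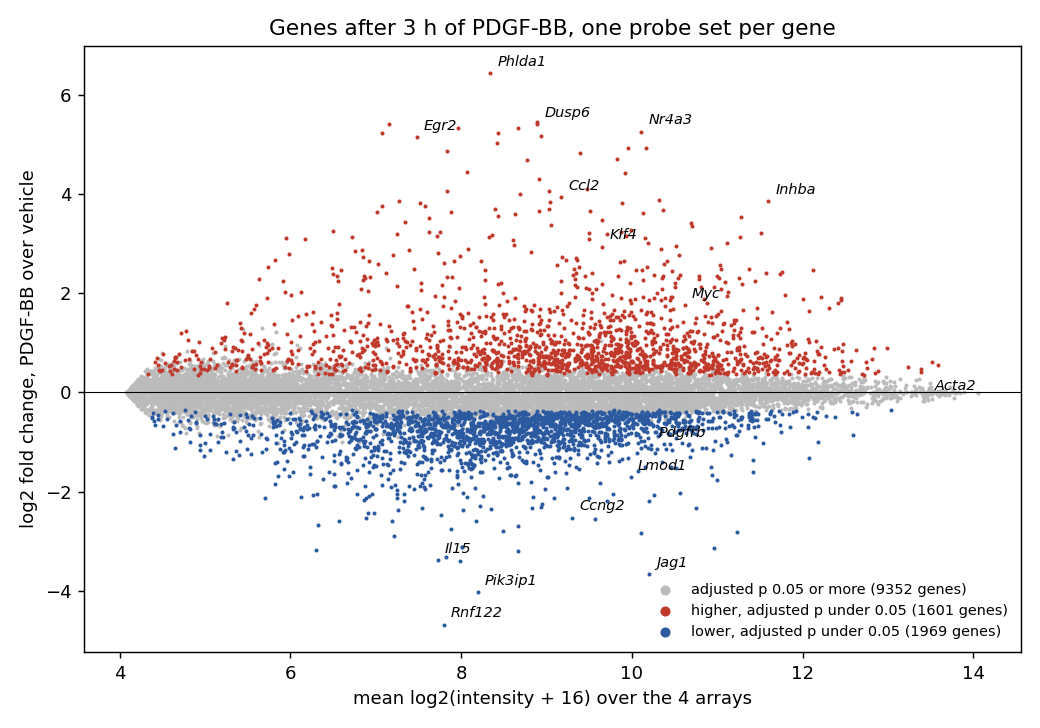
Each point is 1 gene. The horizontal axis gives the mean log2(intensity + 16) of the 4 arrays and the vertical axis the log2 fold change, PDGF-BB minus vehicle. The 1601 genes called higher are red, the 1969 called lower are blue and some genes of the text are named, from Phlda1 at 6.43 to Rnf122 at -4.68.

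Immediate early transcription factors rose as a group. Of 26 measured, 22 were higher and 4 did not pass, also 22 when adjusted over the list alone, and the median log2 fold change was 1.84. All 22 were at least 2-fold higher. Besides Fosl1, Nr4a3 and Egr2, the AP-1 subunit Junb rose by 3.48 (SE 0.08), from 225 ± 2.09 to 2676 ± 12.8 (SD, n = 2). Egr1 rose by 2.34 (SE 0.09) and Myc by 1.76 (SE 0.09). Fos rose by 1.32 (SE 0.09) from a vehicle intensity of 50.3 to 149, and 1 of its 2 probe sets was called. Srf, the serum response factor, had a log2 fold change of 0.03 (SE 0.11, limma adjusted p 0.860), a value whose sign depended on the scaling (-0.11 after quantile normalization). The camera adjusted p of the list was 1.43e-15, and adjusted p = 0.232 with an estimated correlation.

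Feedback regulators of MAP kinases and receptors rose likewise, 17 of 21 higher, 1 lower and 3 not passed, the same numbers when adjusted over the list alone, with a median log2 fold change of 1.78. In addition to Phlda1, Dusp5 and Dusp6, Rgs2, which limits G-protein signalling, rose by 4.93 (SE 0.10), from 191 ± 12.4 to 6302 ± 154 (SD, n = 2). Spry1, a Sprouty inhibitor of receptor tyrosine kinase signalling, was the exception and fell by 2.69 (SE 0.09), from 1013 ± 16.8 to 144 ± 9.19; it is outside the rule for named genes and was picked after its value was seen. The camera adjusted p was 6.46e-10, and adjusted p = 0.481 with an estimated correlation.

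Smooth muscle contractile markers split by gene. Of 25 measured, 8 were lower and 17 did not pass, also 8 when adjusted over the list alone, and the median log2 fold change was -0.13. Lmod1, leiomodin, an actin nucleator of muscle, fell by 1.70 (SE 0.11), from 1818 ± 157 to 548 ± 37.0 (SD, n = 2). Ldb3 and Synpo2, proteins of the contractile apparatus, fell by 0.98 (SE 0.10) and 0.94 (SE 0.09), and smoothelin (Smtn) fell by 0.79 (SE 0.10). The smooth muscle myosin heavy chain gene Myh11 fell by 0.70 (SE 0.13, limma adjusted p 0.0256), in 1 of 2 probe sets. By contrast, Acta2, smooth muscle alpha-actin, was at 11624 ± 455 with vehicle and 10877 ± 107 with PDGF-BB (SD, n = 2), a log2 fold change of -0.10 (SE 0.09, limma adjusted p 0.504). Tagln, which encodes SM22-alpha, was at 10546 ± 328 and 10723 ± 338, a log2 fold change of 0.02 (SE 0.09, limma adjusted p 0.880) that turned to -0.03 after quantile normalization and -0.11 after cyclic loess. For calponin (Cnn1) the log2 fold change was 0.26 (SE 0.08, limma adjusted p 0.0944). The 10 members above an intensity of 8000 in vehicle all missed the threshold, while 8 of the 15 dimmer members fell. Among all 121 genes above 8000, limma called 5 higher and 2 lower, against 1601 and 1969 of all 12922 genes. The list fell by camera (adjusted p 0.0392), and adjusted p = 0.550 with an estimated correlation. That call also ended without vehicle replicate 2 (0.0579) and without PDGF-BB replicate 1 (0.120), and under 4 other settings with camera adjusted p-values of 0.0702 to 0.102. Single genes lost their calls too: without vehicle replicate 1 the limma adjusted p was 0.0531 for Synpo2, 0.0599 for Ldb3, 0.0879 for Smtn and 0.148 for Myh11, without vehicle replicate 2 0.0586 for Synpo2, 0.0641 for Smtn and 0.127 for Myh11, and without PDGF-BB replicate 2 0.0531 for Smtn and 0.0579 for Myh11.

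**Figure D2:**
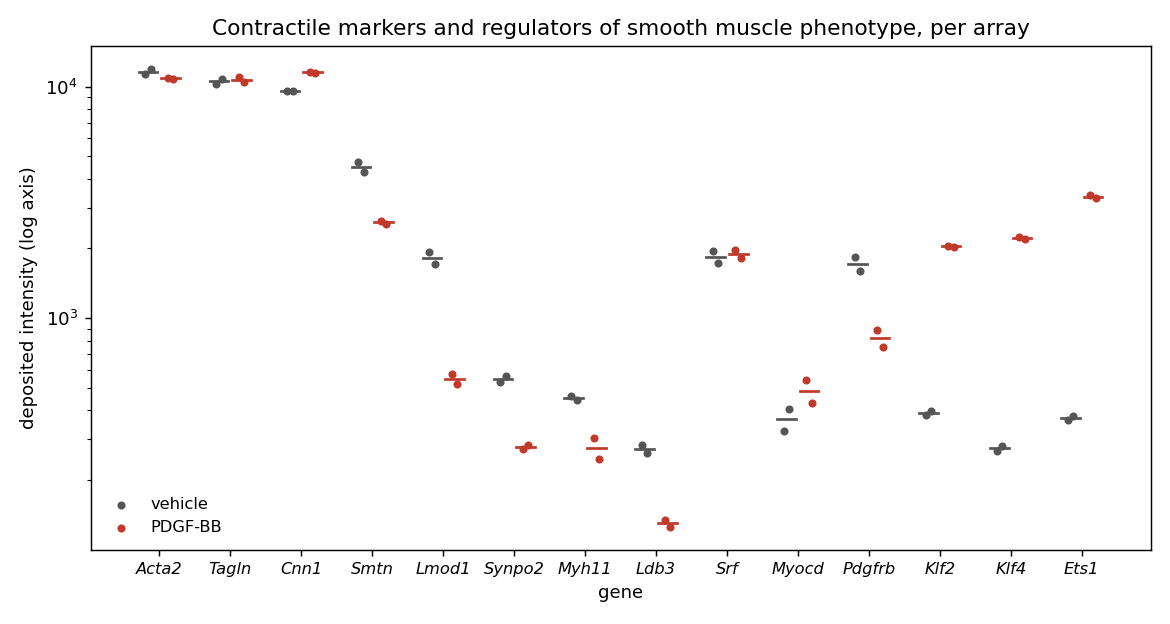
Intensity on each array, on a log axis, for smooth muscle contractile markers, regulators of the phenotype and the receptor gene Pdgfrb; each point is 1 array, 2 per group, and each line a group mean. Acta2 and Tagln lie near 10000 in both groups, Lmod1 lies lower with PDGF-BB (548 against 1818) and Klf4 higher (2214 against 275).

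Of 25 regulators of the smooth muscle phenotype, 11 were higher, 1 lower and 13 did not pass, and 12 higher and 3 lower when adjusted over the list alone. Klf4, a zinc-finger factor that represses contractile genes, rose by 2.94 (SE 0.09), from 275 ± 9.40 to 2214 ± 30.8 (SD, n = 2). Ets1 rose by 3.12 (SE 0.09), Crem, a cyclic AMP-responsive factor, by 2.49 (SE 0.09) and Klf2 by 2.35 (SE 0.09). Klf15, which was outside the rule for named genes and picked after its value was seen, fell by 2.08 (SE 0.12). Myocd, the SRF coactivator myocardin, had a log2 fold change of 0.39 (SE 0.17, limma adjusted p 0.182). The list's median log2 fold change was 0.47, with a camera adjusted p of 0.000365, and adjusted p = 0.550 with an estimated correlation.

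Growth factors and their receptors rose in 14 of 26 cases, with 1 lower and 11 not passed, and 15 higher and 2 lower when adjusted over the list alone. Inhba, the activin A subunit, rose by 3.86 (SE 0.09) to 11769 ± 271 (SD, n = 2), Hbegf, a ligand of the EGF receptor, by 3.42 (SE 0.11), Egfr itself by 2.53 (SE 0.09) and Fgf2 by 1.42 (SE 0.09). Of the PDGF receptors, Pdgfrb fell by 1.05 (SE 0.14, limma adjusted p 0.0105), in 1 of 2 probe sets. Its call ended without vehicle replicate 1 (0.0764), vehicle replicate 2 (0.0546) or PDGF-BB replicate 2 (0.0544). Pdgfra was near background, at 78.5 with vehicle and 82.4 with PDGF-BB, a log2 fold change of 0.06 (SE 0.10, limma adjusted p 0.725) that was -0.0076 without PDGF-BB replicate 1. The list's median was 0.59, its camera adjusted p was 1.25e-05, and adjusted p = 0.550 with an estimated correlation.

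Inflammatory cytokines and NF-kappaB targets rose in 18 of 30 cases and 12 did not pass, with 20 higher when adjusted over the list alone. The chemokines Ccl2, Ccl7 and Cxcl1 rose by 3.94 (SE 0.10), 3.84 (SE 0.09) and 3.38 (SE 0.13) on the log2 scale. Ptgs2, the inducible cyclooxygenase, rose by 3.01 (SE 0.11), from 769 ± 85.7 to 6308 ± 198 (SD, n = 2). The median log2 fold change was 0.73 and the camera adjusted p 4.04e-09, and adjusted p = 0.232 with an estimated correlation.

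Genes of DNA replication and mitosis were lower at this time. Of 28 measured, 19 fell and 9 did not pass, 21 when adjusted over the list alone, and the median log2 fold change was -0.52. The spindle checkpoint kinase genes Bub1b and Bub1 fell by 1.38 (SE 0.10) and 0.91 (SE 0.09), the mitotic kinesin Kif11 by 0.96 (SE 0.09) and Cdc20 by 0.82 (SE 0.09). The camera adjusted p was 9.58e-07, and adjusted p = 0.550 with an estimated correlation. Among G1 cyclins, E2F factors and kinases, 1 of 17 was higher, 6 were lower and 10 did not pass, 1 and 7 when adjusted over the list alone. E2f2 fell by 1.63 (SE 0.10) to 42.3, near background, E2f1 by 1.15 (SE 0.10) and the pocket protein genes Rbl2 and Rb1 by 0.98 (SE 0.10) and 0.67 (SE 0.09). Cyclin D1 (Ccnd1), the partner of Cdk4 and Cdk6, was the member that rose, by 0.47 (SE 0.10, limma adjusted p 0.0342). The list had a median of -0.13 and a camera adjusted p of 0.115. Probe sets of intermediate intensity, 128 to 512, had a median log2 fold change of -0.12 and differed by a median of 0.17 between the PDGF-BB arrays, and the replication list had median intensities of 557 with vehicle and 341 with PDGF-BB. Without vehicle replicate 1 the limma adjusted p was 0.0622 for Bub1, 0.0569 for Kif11, 0.0669 for Cdc20, 0.0598 for Rbl2, 0.1002 for Rb1 and 0.221 for Ccnd1, and without vehicle replicate 2 0.0636, 0.0526, 0.0750, 0.0534, 0.101 and 0.149 for the same genes in that order, while Ccnd1 also missed the threshold without either PDGF-BB array (0.0880 and 0.0765).

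FOXO targets and quiescence genes fell in 13 of 25 cases, 4 rose and 8 did not pass, with 14 lower and 4 higher when adjusted over the list alone. Besides Pik3ip1, the cyclin G2 gene Ccng2 fell by 2.52 (SE 0.10), the insulin receptor substrate Irs1 by 2.12 (SE 0.11) to 9.03, near background, and the CDK inhibitor p27 gene Cdkn1b by 1.36 (SE 0.09), the last from 4355 ± 99.0 to 1692 ± 62.9 (SD, n = 2). The median log2 fold change was -0.48 and the camera adjusted p 0.0392, and adjusted p = 0.550 with an estimated correlation. The list's call also ended without PDGF-BB replicate 1 (0.0861) and under 4 other settings (0.0566 to 0.102).

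Ribosome biogenesis genes and MYC targets rose in 24 of 33 cases and 9 did not pass, with 28 higher and 1 lower when adjusted over the list alone. Rrs1, a ribosome assembly factor, rose by 1.81 (SE 0.08), from 528 ± 1.26 to 1884 ± 22.6 (SD, n = 2), and the nucleolar protein genes Wdr43, Nolc1 and Nop56 by 1.27 (SE 0.09), 1.24 (SE 0.09) and 1.12 (SE 0.09). The median was 0.70 and the camera adjusted p 3.90e-12, and adjusted p = 0.550 with an estimated correlation.

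**Figure D3:**
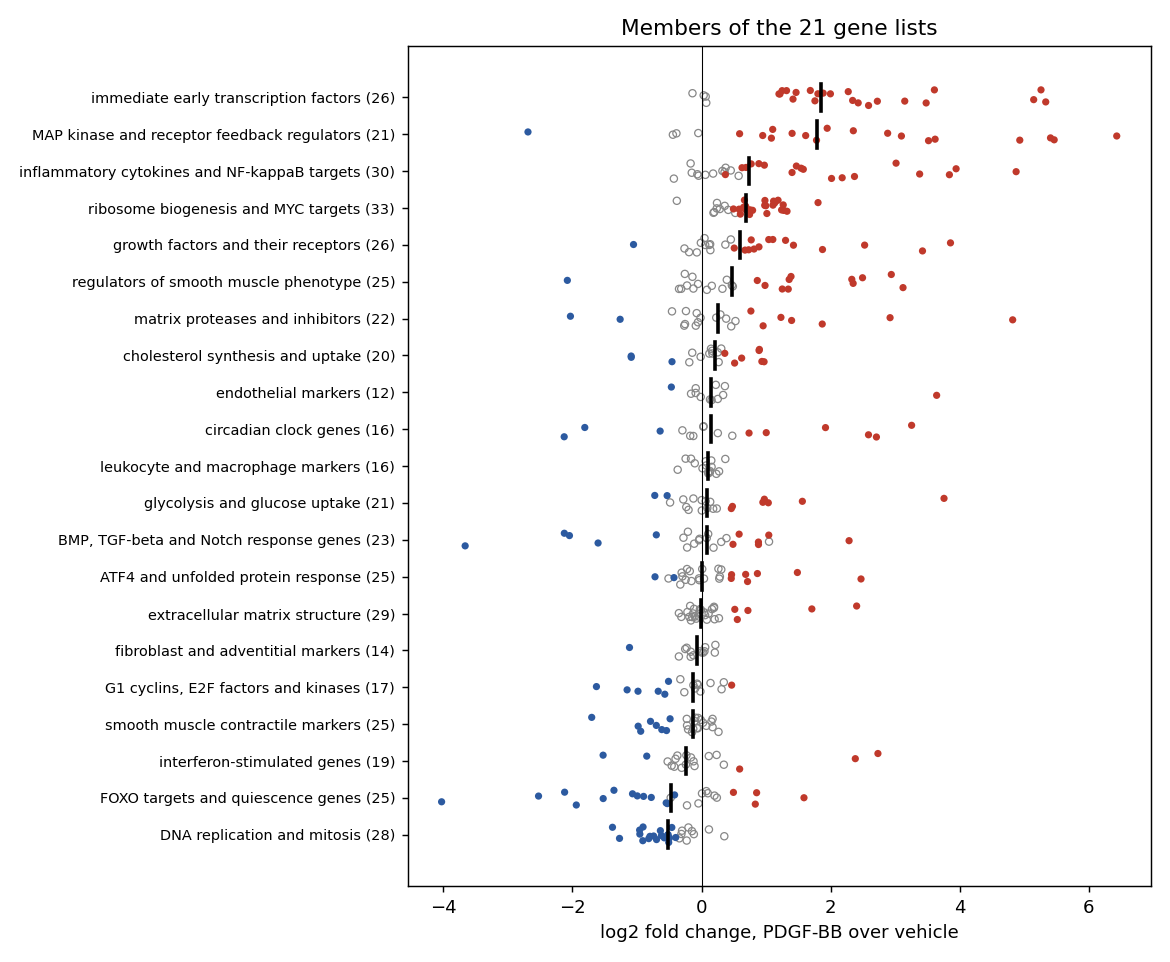
For each of the 21 gene lists, points give the log2 fold change, PDGF-BB minus vehicle, of every measured member (filled where called, open where not) and the black bar their median, with the number of members beside the name; immediate early transcription factors had the highest median (1.84) and DNA replication and mitosis the lowest (-0.52).

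Matrix genes changed singly. Of 29 genes of extracellular matrix structure, 5 rose and 24 did not pass, also 5 when adjusted over the list alone. The matrix Gla protein gene Mgp rose by 2.40 (SE 0.10), tenascin C (Tnc) by 1.71 (SE 0.10), Col18a1 by 0.72 (SE 0.10) and osteopontin (Spp1) by 0.55 (SE 0.09). The list's median was -0.01 and its mean 0.18, and camera, which gave the direction of the mean, had an adjusted p of 0.273. Of 22 matrix proteases and inhibitors, 7 were higher, 2 lower and 13 did not pass, 7 and 3 when adjusted over the list alone. Plaur, the urokinase receptor, rose by 4.82 (SE 0.12), the tissue plasminogen activator gene Plat by 2.92 (SE 0.09), the metalloproteinase inhibitor Timp1 by 1.87 (SE 0.09) and tissue factor (F3) by 1.40 (SE 0.12). This list's median was 0.26 and its camera adjusted p 0.0506, a value that fell to 0.0194 without vehicle replicate 2 and passed under 6 other settings (0.0168 to 0.0430), while the alternatives reached up to 0.150, and adjusted p = 0.550 with an estimated correlation. Spp1 missed the limma threshold in each fit that left out 1 array, in the order of the vehicle and then the PDGF-BB replicates with 0.148, 0.118, 0.0559 and 0.0570, and Col18a1 without either vehicle array (0.0895 and 0.0981).

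Metabolic lists changed in single members. Of 20 genes of cholesterol synthesis and uptake, 7 rose, 3 fell and 10 did not pass, the same numbers when adjusted over the list alone. Insig1, Idi1 and Msmo1 rose by 0.93 (SE 0.09), 0.90 (SE 0.09) and 0.89 (SE 0.09), and Insig2, like Insig1 a regulator that retains SREBP in the endoplasmic reticulum, fell by 1.09 (SE 0.12). The median was 0.21 and the camera adjusted p 0.0392, and adjusted p = 0.550 with an estimated correlation; this call also ended without vehicle replicate 1 (0.0564), vehicle replicate 2 (0.0862) or PDGF-BB replicate 1 (0.0930), and under 5 other settings (0.0564 to 0.0814). In glycolysis and glucose uptake, 7 of 21 rose, 2 fell and 12 did not pass, the same when adjusted over the list alone. Hexokinase 2 (Hk2) rose by 3.76 (SE 0.16) from a vehicle value of 36.4, near background, the glucose transporters Slc2a3 and Slc2a1 by 1.56 (SE 0.09) and 0.97 (SE 0.09), and Pfkp by 0.95 (SE 0.10). The median was 0.09 and the camera adjusted p 0.113, which became 0.0234 with an intensity trend in the variance, the 1 call among 14 alternatives, whose highest value was 0.273, and adjusted p = 0.608 with an estimated correlation. Of 25 genes of the ATF4 and unfolded protein response, 7 rose, 2 fell and 16 did not pass, 8 and 5 when adjusted over the list alone. The amino acid transporters Slc7a1 and Slc7a5 rose by 2.47 (SE 0.09) and 1.49 (SE 0.14), Chac1 by 0.87 (SE 0.10) and Mthfd2 by 0.71 (SE 0.09), with a median of 0.01 and a camera adjusted p of 0.308 for the list. Without vehicle replicate 1 the limma adjusted p was 0.0588 for Insig1, 0.0652 for Idi1, 0.0633 for Msmo1, 0.0576 for Insig2, 0.0569 for Slc2a1, 0.0656 for Pfkp, 0.0578 for Chac1 and 0.0821 for Mthfd2. Without vehicle replicate 2 it was 0.0534, 0.0551, 0.0582 and 0.0593 for the cholesterol genes in that order, 0.0619 for Pfkp, 0.0713 for Chac1 and 0.0919 for Mthfd2, and without PDGF-BB replicate 2 it was 0.0517 for Slc7a5.

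Signalling response genes went both ways. Of 23 BMP, TGF-beta and Notch response genes, 6 rose, 5 fell and 12 did not pass, 7 and 5 when adjusted over the list alone. Besides Jag1, the BMP target Id2 fell by 2.12 (SE 0.14) and the Notch target Hey1 by 2.05 (SE 0.10) to 38.0, near background, while the receptor gene Notch1 rose by 2.29 (SE 0.09). The list's median was 0.08, its mean -0.12, and camera gave the sign of the median with an adjusted p of 0.507. Of 19 interferon-stimulated genes, 3 rose, 2 fell and 14 did not pass, 3 and 3 when adjusted over the list alone. Usp18 and Oasl rose by 2.73 (SE 0.16) and 2.38 (SE 0.10) from vehicle values of 29.2 and 23.7, near background, and Ifit2 and Irf1 fell by 1.52 (SE 0.09) and 0.85 (SE 0.12). The median was -0.23, the mean 0.03, and camera gave the sign of the median with an adjusted p of 0.405. Irf1 missed the limma threshold without vehicle replicate 1 (0.0826) or 2 (0.0912). Of 16 circadian clock genes, 6 rose, 3 fell and 7 did not pass, 7 and 3 when adjusted over the list alone. Npas2, Nfil3 and Bhlhe40 rose by 3.25 (SE 0.12), 2.71 (SE 0.09) and 2.59 (SE 0.11), and the clock output gene Dbp fell by 2.13 (SE 0.09), with a list median of 0.14 and a camera adjusted p of 0.117. The vehicle values of Npas2 (13.4) and Bhlhe40 (37.4) and the PDGF-BB value of Dbp (40.6) were below 80.3, so the size of these changes depends on values near background.

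Endothelial and leukocyte markers were mostly dim, fibroblast and adventitial markers less so. Of 12 endothelial markers, 9 were at or below 80.3 in both groups, 1 was higher, 1 lower and 10 did not pass, the same when adjusted over the list alone. The higher gene was Flt1, a VEGF receptor, with 3.64 (SE 0.14), from 50.8 ± 9.10 to 816 ± 82.4 (SD, n = 2). Its vehicle value was below 80.3, so the size of the change depends on values near background. The lower gene was Esam, which fell by 0.47 (SE 0.09, limma adjusted p 0.0249) and missed the threshold in each fit that left out 1 array (0.169, 0.178, 0.0552 and 0.0707, vehicle replicates first). Nos3 and Sox18 were at or below 80.3 in both groups and did not pass. Of 16 leukocyte and macrophage markers, 12 were at or below 80.3 in both groups. None passed limma's threshold, also when adjusted over the list alone. The lowest unadjusted limma p was 0.0831, for Cd14 (1434 with vehicle, log2 fold change -0.25, SE 0.11). Ptprc and Cd53 were at or below 80.3 in both groups, and Aif1 had a log2 fold change of 0.13 (SE 0.09), which was -0.11 as the mean of its probe sets. Of 14 fibroblast and adventitial markers, 6 were at or below 80.3 in both groups. Scara5 was called lower and 13 did not pass, the same when adjusted over the list alone. Scara5 was at or below 80.3 in both groups, at 77.2 with vehicle and 26.9 with PDGF-BB, so the size of its change is not given, and its call ended without vehicle replicate 2 (0.0526). Lum (-0.35, SE 0.09), Mfap5 (-0.25, SE 0.09) and Col14a1 (-0.23, SE 0.09) did not pass. Their vehicle means were 108, 379 and 4213. The medians of the endothelial, leukocyte and fibroblast lists were 0.14, 0.11 and -0.07, with camera adjusted p-values of 0.265, 0.431 and 0.431.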

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

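The array's own control probe sets for rat hexokinase, which were outside the comparison, were higher with PDGF-BB. Their log2 fold changes were 0.86 at the 3′ end, 0.81 in the middle and 0.998 at the 5′ end of the transcript (SE 0.13, 0.12 and 0.12), with limma adjusted p-values of 0.0147, 0.0145 and 0.00969, and both PDGF-BB arrays lay above both vehicle arrays. The Hk1 gene's own probe set had a log2 fold change of 0.48 (SE 0.10, limma adjusted p 0.0321). No explanation was tested for the difference in size.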

How the results depend on the processing

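Cyclic loess normalization was chosen after seeing the data; all other alternatives were planned. Of the 97 named genes called with all arrays, quantile, median and cyclic loess scaling, the intensity trend and the robust prior kept 97. The replicate block and pseudocount 1 each kept 95, and the mean of all probe sets 96. No called gene was called in the opposite direction under any alternative. The call was kept by 74 of the 97 named genes without vehicle replicate 1, 75 without vehicle replicate 2, 94 without PDGF-BB replicate 1 and 90 without PDGF-BB replicate 2, and by 72 in all 4 fits. The lone array of a group was assumed to vary like the other group. Over these fits, 1272 to 4223 probe sets were called, 781 to 1709 higher and 491 to 2514 lower, and 786 to 2683 genes, 488 to 1057 higher and 298 to 1626 lower. A 2-fold minimum left 1779 probe sets, 998 higher and 781 lower. Other settings called 2578 (pseudocount 1) to 4771 genes (quantile normalization), and the share of higher genes was 44.8% as deposited and 39.8% to 52.6% under the scalings and 39.4% to 62.1% with 1 array left out. Probe sets near background carry little information: limma called 5.02% of those under an intensity of 32 and 38.9% of those at 512 to 2048.

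The lists of immediate early factors, feedback regulators, phenotype regulators, growth factors, inflammatory genes, replication and mitosis, and ribosome biogenesis were called under all 14 alternatives other than the estimated correlation. With it, camera adjusted p-values were 0.232 for immediate early factors and inflammatory genes, 0.481 for feedback regulators, and 0.550 for contractile markers, phenotype regulators, growth factors, replication and mitosis, FOXO targets, ribosome biogenesis and cholesterol genes. That form of the test rests on 2 residual degrees of freedom and has little power here. The estimated correlation was also far above the preset 0.01 for some of these lists, at 0.68 for ribosome biogenesis, 0.41 for replication and mitosis and 0.34 for phenotype regulators. The 14 alternatives all kept the preset, so they do not test these calls against correlation between genes. The robust prior was not run for lists, since camera does not take it. Camera adjusted p-values of lists that crossed the threshold follow; the cause was not tested. Contractile markers reached 0.0795 with medians subtracted, 0.102 without the dimmer 50% of probe sets, 0.0786 without the dimmest 25%, 0.0702 with the mean of probe sets, and 0.0364 to 0.120 with 1 array left out. FOXO targets reached 0.0764 with quantile normalization, 0.102 and 0.0786 with the filters, 0.0566 with the mean of probe sets, and 0.0104 to 0.0861 with 1 array left out. Cholesterol genes reached 0.0814 with quantile normalization, 0.0618 with medians subtracted, 0.0564 without the dimmest 25%, 0.0667 with cyclic loess, and 0.0406 to 0.0930 with 1 array left out. Matrix proteases gained a call at 0.0168 and 0.0336 with the filters, 0.0211 with the intensity trend, 0.0363 with pseudocount 64, 0.0413 with the mean of probe sets, and ranged from 0.0194 to 0.0979 with 1 array left out. Glycolysis gained one at 0.0234 with the trend. The direction of uncalled lists turned for leukocyte markers without the dimmer 50% (0.848), and for leukocyte (0.128 to 0.979) and fibroblast markers (0.189 to 0.979) with 1 array left out.

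Among the named genes, signs turned for those that were uncalled throughout: Tagln with quantile normalization (-0.028) and cyclic loess (-0.11) and with 1 array left out (-0.0081 to 0.056), Srf with quantile normalization (-0.11) and with 1 array left out (-0.052 to 0.12), Pdgfra with 1 array left out (-0.0076 to 0.12), and Aif1 with the mean of probe sets (-0.11). Of the 3570 genes called in the main fit, 3 changed sign with the mean of probe sets, and 0 were called the other way.

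With the replicate number as a block, 2992 genes were called, and 2894 of the 3570 genes called in the main fit kept their call and direction. Matrix proteases reached a camera adjusted p of 0.0430 and cholesterol genes 0.0586, and no other list changed its call. The main fit, set beforehand, did not take the numbers as pairs, since nothing in the labels says that they mark a shared culture or day. Same-numbered arrays did not deviate together either (r = -0.098 across probe sets).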

Other observations

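A scan of symbol families pointed to the cilium genes. The camera test of the other cilium genes and the intensity test of the Ift and Cep genes were then set before their results were seen. The intensity test of the 35 other cilium genes was not among the tests set beforehand. The tests of replication genes and of the bright markers without a dimmer probe set were chosen after the results were seen. So were those of the cilium list without Wdr19, Wdr35, Traf3ip1 and Cluap1.

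Genes of intraflagellar transport and of centrosomal proteins, with symbols beginning Ift and Cep, were mostly lower with PDGF-BB. Of 40 such genes, 21 fell, 3 rose and the median log2 fold change was -0.53. Ift70b fell by 2.12 (SE 0.14), Cep57 by 1.51 (SE 0.11), Ift88, a core transport protein, by 0.53 (SE 0.09) and Cep290, a transition zone protein, by 1.13 (SE 0.11); Ift70b and Cep290 reached 57.7 and 34.0 with PDGF-BB, near background. The scan that led to them covered 174 families of at least 10 genes, of which camera called 0 after adjustment and 27 at an unadjusted p under 0.05. The Ift and Cep families had camera adjusted p-values of 0.0557 and 0.0596, and both adjusted p = 0.995 with an estimated correlation. They did not stand apart in the scan. The Mcm family, also lower, shared the 0.0557. The family with prefix H, lower, and the Klf and Tnfrsf families, both higher, shared the 0.0596. A list of 35 other cilium genes was then tested, without Ift and Cep genes and without Cc2d2a and Lztfl1. Of these, 12 fell and 1 rose, with a median of -0.39, a camera p of 1.18e-05, and p = 0.337 with an estimated correlation. Ttc8 and Bbs2, both of the BBSome, fell by 1.30 (SE 0.13) and 1.12 (SE 0.10), Bbs2 to 72.0, near background. The list was not free of intraflagellar transport genes: it held Wdr19, Wdr35, Traf3ip1 and Cluap1, of the transport complexes, and motor genes such as Dync2h1 and Kif3a. Without the first 4, but with the motor genes, 11 of 31 fell and the camera p was 1.44e-05, and p = 0.312 with an estimated correlation. The Cfap family of the same scan, genes associated with cilia and flagella, had a median of 0.02 over 16 genes and a camera p of 0.776. By limma 3 of them fell and 0 rose, and the 3 were among the 7 above 80.3 in at least 1 group. An offset between the arrays that varies with intensity was examined by subtracting the median of the 200 genes nearest in intensity. This took the Ift and Cep genes from -0.53 to -0.42. These genes were picked for being low, so neither that value nor their rank among random lists can decide about the offset. The other cilium genes, not picked by the scan, had -0.25 after the subtraction, with or without the 4 genes of the complexes. The 2.5th percentiles were -0.18 and -0.19 over 10000 random lists matched on intensity. For the other cilium genes, these values argue against the offset as the whole cause. The random genes were drawn independently, so the range of the random lists may be too narrow for genes that vary together. Part of the cilium genes may be lower after PDGF-BB, a hypothesis that no independent samples tested; whether the class shifts, the correlation between these genes and the authors' scaling stay open.

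Replication and mitosis genes were lower in 19 of 28 cases at 3 h, and 9 did not pass. Their products are needed for the cell division that a mitogen induces. The list's call was lost with an estimated correlation (camera adjusted p 0.550), a test of little power with 2 residual degrees of freedom. Whether the group moved as a whole stays open. Subtracting the median of the 200 genes nearest in intensity took the list's median from -0.52 to -0.42. The shift shared by genes of like intensity was therefore smaller than the list's median. The random lists had -0.19 at the 2.5th percentile, but they were drawn from unrelated genes. This list had an estimated correlation of 0.41 and was tested after it was seen to be low, so that percentile is not counted. Without it no spread remains to judge the -0.42, so the test cannot decide about an intensity-dependent offset. A single PDGF-BB array as the cause is argued against, since the list's median difference from the vehicle mean was -0.47 on replicate 1 and -0.58 on replicate 2. No biological explanation was tested, and no later time was analysed here.

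The 10 contractile markers above 8000 in vehicle all missed the threshold, as did 7 of the 15 dimmer ones, and signal compression near the top of the scale could hide a decrease in the bright ones. Where Tpm1, Cald1 and Vcl had dimmer probe sets, at 100 to 8000, these had a median log2 fold change of -0.078 over 6 probe sets. This leaves compression open for these 3 genes too, since the probe sets of Cald1 and Vcl, at 7289 and 7025, were hardly dimmer, those of Tpm1 at 101 and 115 lay near background, and only Tpm1 at 787 (-0.18) and 940 (-0.16) lay between. For 7 genes, Acta2, Tagln, Cnn1, Tpm2, Myl9, Flna and Csrp1, no dimmer probe set existed. Cnn1 was higher on both PDGF-BB arrays (11585 and 11489) than on both vehicle arrays (9597 and 9622), though it missed the threshold. For the others, compression and an unchanged transcript level cannot be told apart. No gene above 8000 in vehicle was called lower by at least 2-fold, of 121 such genes. Of all 12922 genes 484 were. Calls of any size were also scarcer among the bright genes, with 5 higher and 2 lower of 121, against 27.6% of all genes called. Whether compression makes calls scarcer there was not tested. A transcript that outlasts 3 h would also show no decrease, which was not tested.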
